A study of Mus musculus with 12 samples.

How the data were processed

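Each of the 12 samples was 1 scan of an Arraystar mouse lncRNA and mRNA array read in a single colour (Cy3). Per the labels, total RNA of a dissected region was depleted of ribosomal RNA, then amplified and labelled by random priming. Per the file headers and the submitters' processing notes, the authors extracted spot values with Agilent Feature Extraction 11.0.1.1. The deposited scanner files give each spot's intensity as a processed signal, a median signal and a median local background, with marks for outlier, saturated and well-above-background spots. Per the file headers, the processed signal had background subtracted and a spatial trend removed by the scanner software. The authors also deposited a value table of 60804 probes on the log2 scale. Set against the scanner values of the same arrays it had slopes of 0.972 to 1.02 and column medians of 8.48 to 8.49, and sorted values differed between columns by 0.00158 at the median rank, as quantile-normalized, uncentred values would. The step by which it was made is not given in the sources used here.

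The values tested were log2 processed signal minus the 75th percentile of each scan. Spots marked as non-uniform or population outliers (11 to 80 per scan) were left out and copies of a probe averaged. Control spots and 15 probes named as negative were left out. A probe was tested if it was well above background on all scans of at least 1 region, which kept 56572 probes, and 51264 were so on all scans. R 4.3.3 and limma 3.58.1 (lmFit, eBayes) were used, with 1 mean per region, a spread shared by all regions and Benjamini-Hochberg adjustment. A probe counted as different at an adjusted p under 0.05 and an absolute log2 difference of at least 1. A probe counted as region-specific if it met this in the same direction against each of the 3 other regions. The test over all 4 regions used the adjusted p alone.

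The design, also fixed beforehand, counted 12 arrays. Scans were then compared, and 2 pairs were found to differ by less than the spread of copies within a scan. The 2 scans of each pair were averaged before fitting, which left 10 arrays and 6 residual degrees of freedom. Fits of all 12 scans and of first scans alone were run as alternatives. Labels do not tie arrays to animals, although the series text gives 3 mice, so p-values measure the spread between these arrays.

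Slides were inferred from the scan times, of which there were 4. Replicates 1 and 2 of all 4 regions had scan times 1 and 2, taken as slides 1 and 2. Replicate 3 of the olfactory bulb and the hypothalamus had scan time 3, taken as slide 3. Replicate 3 of the hippocampus and the cerebellum had scan time 4. These scans were averaged with replicate 1 and counted on slide 1. For the 10 arrays, the replicate block and the slide block are therefore 1 fit. The labels do not say whether replicate numbers also follow the animals. If they do, effects named for the slide below cannot be told apart from differences between animals. Deviations from region means correlated between same-numbered arrays at r 0.124 to 0.757 across probes. These 13 pairs are not independent, because the deviations of a region add up to 0 and those of 2 arrays mirror each other. The arrays were therefore renumbered within regions in all 24 ways, a test chosen after the data were seen: the mean r was 0.478 as numbered, at most 0.308 in another way and -0.0206 on average over the others. The numbers were taken as pairing the arrays. Within-slide differences were computed too.

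No column of the files pairs the array-design IDs with genes, and no table used here does. The 15 RefSeq accessions in the files all matched a gene. Of 625 genes in 35 lists, 0 had a naming probe, so tests of gene lists, counts per gene, the coding against noncoding comparison and neighbouring gene pairs were not run. The rule for named genes, fixed before the data were examined, ranked genes and could not be applied to probes without gene names. Its ranking was therefore carried over to probes: per region, the region-specific array-design IDs with the largest value of their smallest log2 difference to another region, among those well above background on at least 1 scan of each region. Of these, 2 higher and 2 lower are given, with the top lincRNA-named probe of the regions that had one. The 15 named genes are all reported, each for its highest against its lowest region, a pair chosen from the values. The files use the mm9 build for probe names, and no coordinates are given.

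Alternatives were quantile normalization, the authors' value table, no filter on dim probes, only probes well above background on all scans, the replicate block, eBayes with trend and robust variance, leaving out each array, and fits of 2 regions alone. Normexp (offset 50) was run on the median spot signal, as no mean spot signal was in the files. After the data were seen, 2 corrections for position on the array were added, over 128 tiles of spots. The code was tested on simulated data for each region against the other 3, with 56572 probes, 50 of them changed at each fold. For the olfactory bulb it recovered 0 of 50 at 1.5-fold, 29 of 50 at 3-fold, 45 of 50 at 4-fold and 41 of 50 at 8-fold, and called 4 of 56372 unchanged probes. For the cerebellum it recovered 0, 36, 38 and 44 of 50 at these folds, and called 1 unchanged probe. For the hypothalamus it recovered 0, 39, 40 and 48 and called 4 unchanged probes, and for the hippocampus 0, 35, 40 and 43 and called 7. Under the stricter rule for region-specific probes it recovered 25, 35 and 41 at 3-, 4- and 8-fold for the olfactory bulb, 29, 35 and 46 for the hypothalamus, 30, 35 and 42 for the hippocampus and 32, 32 and 39 for the cerebellum, none at 1.5-fold, and called at most 2 unchanged probes per region. A 1.5-fold change lies under the cut on the log2 difference, so its 0 recovered probes follow from the cut. The same cut limits the calls of unchanged probes. The test over all 4 regions, which has no such cut, was not scored on simulated data. The simulation held no slide or position effect.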

Results

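Transcript levels were measured in 4 brain regions of male BALB/c mice aged 10 weeks, with the aim, per the series title, of profiling long noncoding RNAs and messenger RNAs. The regions were the olfactory bulb, which receives input from the nose, the hypothalamus, which governs hormones and body state, the hippocampus, a centre of memory, and the cerebellum, a centre of motor control. Each region was represented by 3 scans of a 1-colour Arraystar mouse array, 12 scans in all. Between 87.85% and 93.15% of the 60915 probes were well above background on a scan, and no probe was saturated. The median processed signal of a scan lay between 290.7 and 443.2 intensity units. For arrays, the number of arrays limits the precision of each value.

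The hippocampus and the cerebellum were each counted as 2 arrays rather than 3, because 2 of their 3 scans were nearly identical. Replicates 1 and 3 of the hippocampus differed over 14991 bright probes with an SD of 0.0277 on the log2 scale, and replicates 1 and 3 of the cerebellum with an SD of 0.0262. The spread of the copies of a probe within a scan (SD) was 0.0779 on the scan where it was smallest, and every other pair of scans of 1 region differed with an SD of 0.314 to 0.51. The hippocampus pair shared 35 spots marked as non-uniform and the cerebellum pair shared 5, whereas no other pair of scans shared more than 1. If spots were marked independently, 0.0411 and 0.00289 shared spots would be expected. The 2 scans of each pair were therefore averaged and counted as 1 sample. The comparisons below therefore count 10 arrays: 3 of the olfactory bulb, 3 of the hypothalamus, 2 of the hippocampus and 2 of the cerebellum.

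**Figure D1:**
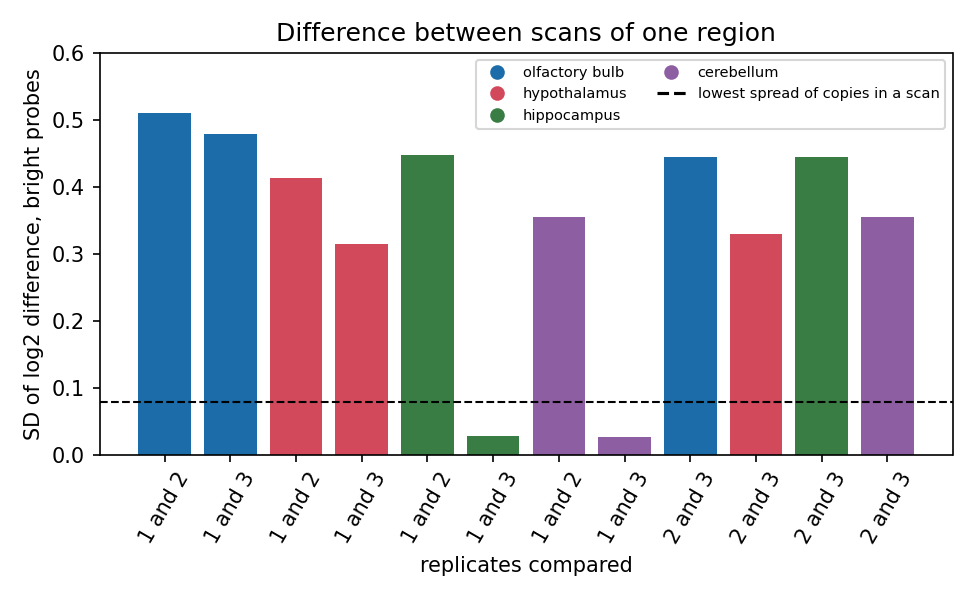
SD of the log2 difference between scans of 1 region over bright probes (y axis) for each pair of replicates (x axis), coloured by region; the dashed line is the smallest spread of copies of a probe within a scan, 0.0779. Replicates 1 and 3 of the hippocampus (0.0277) and of the cerebellum (0.0262) lie below the line, and the other pairs lie at 0.314 or above.

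The 4 regions differed broadly. Of 56572 probes tested, 20406 (36.1%) differed between the regions at an adjusted p under 0.05, and the region means of 3965 of these spanned at least 4-fold and of 1717 at least 8-fold. The cerebellum was the lowest region for 34.9% of the differing probes and the hippocampus for 31.7%, whereas the olfactory bulb was the lowest for 15.6%. The highest region was the cerebellum for 28.7%, the hypothalamus for 28.4%, the olfactory bulb for 27.3% and the hippocampus for 15.5%. Each of the 10 arrays correlated most closely, across probes, with another array of its own region. The first principal component (30.6% of the variance) set the cerebellum apart and the second (24% of the variance) set the olfactory bulb apart. Component 3 (17.6%) followed the slide more than the region, which explained 60.6% and 45.9% of it when each was taken alone. For component 4 (12.7%) these values were 30% and 61.7%. With slide as a block, 30538 probes differed between the regions, including 20147 of the 20406.

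**Figure D2:**
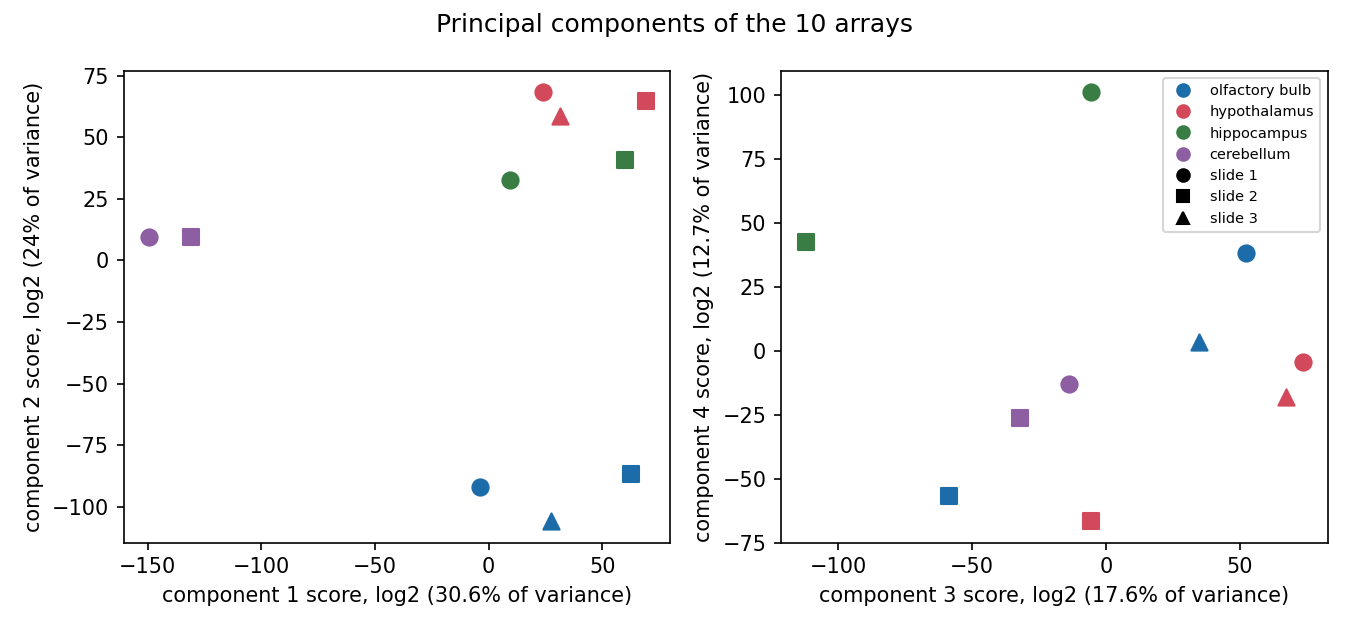
Scores of the 10 arrays on the first 4 principal components of log2 signal (axes, with the percent of variance), coloured by region, with the marker showing the slide. The cerebellum arrays lie apart on component 1 (30.6%) and the olfactory bulb arrays on component 2 (24%).

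In the olfactory bulb, 893 probes were at least 2-fold higher than in each of the other 3 regions and 174 were at least 2-fold lower than in each. The probe ASMM10P027469 stood at 3.91 ± 0.10 (SD, n = 3; log2 signal relative to the 75th percentile of the array) in the olfactory bulb and at -1.43 in the next region, the cerebellum, a 40.6-fold difference (adjusted p of the contrast with the other regions 2.25e-08). ASMM10P041204 stood at 0.68 ± 0.04 (SD, n = 3), higher than in each other region, but was well above background on only 1 of 3 hippocampus scans. Its measured difference from the mean of the others depended on the background correction, at 6.57 as reported and 4.72 under normexp. ASMM10P033263 was lower in the olfactory bulb, with a contrast of -4.23 (SE 0.08), and so was ASMM10P033261, a dim probe at -5.02 ± 0.75 (SD, n = 3), with one of -3.77 (SE 0.28), or -2.63 under normexp. Counted apart from these sets, which they can overlap, 95 probes were well above background on all scans of the olfactory bulb and on no scan of another region. Against the mean of the other 3 regions, 2096 probes were higher and 1043 lower, or 2094 and 1103 with slide as a block. Within slides, before any test, 2376 probes were 2-fold higher and 2743 lower on slide 1, and 2208 higher and 3244 lower on slide 2. Without olfactory bulb replicate 1, the probes lower than in each other region numbered 392 rather than 174, and under normexp background correction 103, with 1370 rather than 2096 higher than the mean of the others.

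In the hypothalamus, 759 probes exceeded each other region by at least 2-fold and 229 fell short of each. ASMM10P047574 reached 7.35 ± 0.05 (SD, n = 3) in the hypothalamus and -1.89 in the hippocampus, the next region, a 606-fold difference (adjusted p of the contrast with the other regions 2.17e-07). ASMM10P021540 reached 5.80 ± 0.23 (SD, n = 3) against -3.26 in the hippocampus, a 536-fold difference (adjusted p of the contrast with the other regions 6.98e-08), and this contrast was 10.09, or 9.17 under normexp. Among probes lower in the hypothalamus, ASMM10P037905 had a contrast of -4.43 (SE 0.11) and ASMM10P011210 of -4.15 (SE 0.07), or -3.41 under normexp. In the hypothalamus, 44 probes were well above background on all scans and on none elsewhere. Against the mean of the other regions, 1960 probes were higher and 1234 lower, or 1981 and 1310 with slide as a block, and under normexp 796 were lower. Within slides, 2225 probes were 2-fold higher and 1931 lower on slide 1, and 2107 higher and 1951 lower on slide 2.

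In the hippocampus, 477 probes were at least 2-fold higher than in each other region, the fewest of the 4 regions, and 297 were at least 2-fold lower. ASMM10P049924 stood at 4.59 ± 0.15 (SD, n = 2) in the hippocampus against -1.21 in the hypothalamus, a 55.5-fold difference (adjusted p of the contrast with the other regions 1.09e-07). ASMM10P016670 lay 7.81 (SE 0.82) above the other regions, or 6.295 under normexp, and was well above background on only 2 of 3 olfactory bulb scans. ASMM10P030753 was lower in the hippocampus with a contrast of -6.03 (SE 0.15), or -4.47 under normexp, and ASMM10P046725 with one of -4.96 (SE 0.11), or -4.29 under normexp. In the hippocampus, 12 probes were well above background on all scans and on none elsewhere. Another 137 were well above background on no hippocampus scan and on all scans of the 3 other regions. This count was 93 for the cerebellum, also with 2 arrays, and 18 for the olfactory bulb and 8 for the hypothalamus, with 3 arrays each. Against the mean of the others, 1441 were higher and 1507 lower, or 1479 and 1579 with slide as a block. Within slides, 1940 probes were 2-fold higher and 1694 lower on slide 1, and 2416 higher and 2634 lower on slide 2. The balance of higher and lower probes rested on single arrays: without hippocampus replicate 1, 401 probes were higher and 487 lower than in each other region, and under normexp 379 were higher and 144 lower, with 811 rather than 1507 lower than the mean of the others.

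In the cerebellum, 1021 probes were at least 2-fold higher and 1218 at least 2-fold lower than in each other region. The lower count was the highest of the 4 regions under each setting run, whereas without cerebellum replicate 1 the higher probes numbered 840 in the cerebellum and 879 in the olfactory bulb. ASMM10P011114 stood at 7.14 ± 0.05 (SD, n = 2) in the cerebellum against -2.15 in the hypothalamus, a 626-fold difference (adjusted p of the contrast with the other regions 1.31e-08). ASMM10P028337 lay 8.18 (SE 0.08, adjusted p 5.52e-09) above the other regions, or 7.40 under normexp, and 154-fold above the hypothalamus, the next region. ASMM10P019065 stood at -2.14 ± 0.23 (SD, n = 2) in the cerebellum against 5.33 in the hypothalamus, its next lowest region. ASMM10P037463 stood at -7.08 ± 1.44 (SD, n = 2) and was well above background on only 1 of the 3 cerebellum scans, so the size of its difference is uncertain: the contrast was -4.26 under normexp, -8.02 without cerebellum replicate 1 and -5.99 without replicate 2. In the cerebellum, 65 probes were well above background on all scans and on none elsewhere. Against the mean of the others 2090 were higher and 2895 lower, or 2342 and 2925 with slide as a block. Within slides the balance turned: 2616 probes were 2-fold higher and 3943 lower on slide 1, whereas 5259 were higher and 3052 lower on slide 2.

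**Figure D3:**
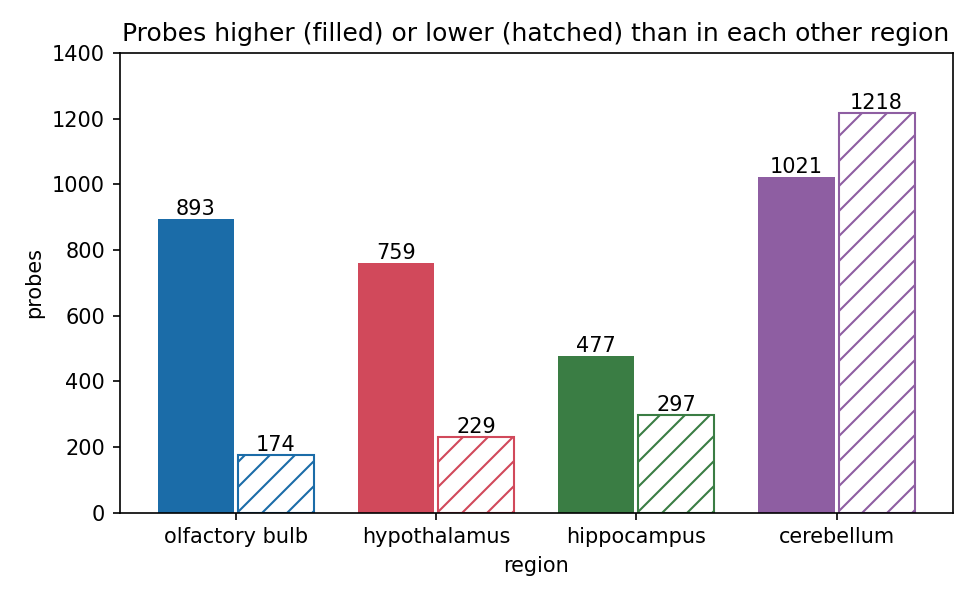
Number of probes (y axis) at least 2-fold higher (filled bars) or lower (hatched bars) than in each of the other 3 regions, for each region (x axis), at an adjusted p under 0.05 per pair. The cerebellum has more lower (1218) than higher (1021) probes, and the olfactory bulb has 893 higher against 174 lower.

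Pairs of regions that included the cerebellum differed in the most probes. The cerebellum differed at 2-fold or more from the hypothalamus in 5991 probes, from the hippocampus in 5775 and from the olfactory bulb in 5327. The hypothalamus and the hippocampus differed in the fewest, 3620 (2147 higher in the hypothalamus, or 1390 under normexp, and 1473 higher in the hippocampus). Their region means correlated at r = 0.974 across probes, which are not independent replicates. The olfactory bulb differed from the hippocampus in 4088 probes (2566 higher in the olfactory bulb, or 1587 under normexp). It differed from the hypothalamus in 4370 probes, 2352 of them higher in the olfactory bulb and 2018 lower, a balance that turned to 2167 and 2347 without olfactory bulb replicate 1. On each slide that held the regions compared, 100% of the called probes had the called direction, by construction of calls from these same arrays.

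Genes were named for 15 probes, each printed in 20 copies. They are mostly housekeeping genes of the kind used as references, and 8 of the 15 differed between the regions. Actb, which encodes cytoskeletal beta-actin, stood at 3.31 ± 0.02 (SD, n = 2) in the cerebellum, 2.1-fold below the hippocampus (log2 1.07, SE 0.11, adjusted p 0.00023), and kept this direction under quantile normalization and normexp. Ldhal6b, of the lactate dehydrogenase family, stood at -1.19 ± 0.11 (SD, n = 3) in the olfactory bulb. This was 2.6-fold above the hypothalamus as reported (adjusted p 0.000871), and above it under quantile normalization and normexp too. Hprt, a purine salvage enzyme, was 1.78-fold higher in the hypothalamus than in the cerebellum (log2 0.83, adjusted p 0.000457), a difference of 0.48 under quantile normalization (adjusted p 0.0122). Tuba1b, an alpha-tubulin, was 1.73-fold higher in the hypothalamus than in the cerebellum (log2 0.79, adjusted p 0.000684), but by 0.29 under quantile normalization, where the call was lost (adjusted p 0.0965). B2m, the light chain of class I histocompatibility molecules, was higher in the olfactory bulb than in the cerebellum by 0.66 on the log2 scale (SE 0.10, adjusted p 0.0018). It was also higher under quantile normalization and normexp. Gusb, a lysosomal enzyme, was 1.69-fold higher in the olfactory bulb than in the hippocampus (adjusted p 0.00188), and higher under quantile normalization and normexp.

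Tbp, the TATA-binding protein, was 1.77-fold higher in the cerebellum than in the hippocampus (adjusted p 0.00527), and so was G6pd2, a glucose-6-phosphate dehydrogenase gene (1.77-fold, adjusted p 0.000411), both also under quantile normalization and normexp. Tfrc, the transferrin receptor, differed by at most 0.14 on the log2 scale (adjusted p 0.437), and Gk, glycerol kinase, by at most 0.30 (SE 0.235, adjusted p 0.429), and neither passed the test. With slide as a block, 13 of the 15 genes differed between the regions: Nono (adjusted p 0.00445), Gapdh (0.00808), Rpl13a (0.0013), Ppia (0.0278) and Hsp90ab1 (0.00122) joined the 8. The Gapdh difference between hypothalamus and olfactory bulb was 0.22 as reported (adjusted p 0.178) but 0.0055 under quantile normalization (adjusted p 0.984). Ppia was 0.26 higher in the hypothalamus than in the cerebellum on the log2 scale (adjusted p 0.0696), but this turned to -0.22 under quantile normalization (adjusted p 0.0955). Probes of Actb, Gapdh, Tuba1b, Ppia, Rpl13a, G6pd2 and Ldhal6b can bind transcripts of close relatives or of processed copies, so their values are uncertain in that respect.

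**Figure D4:**
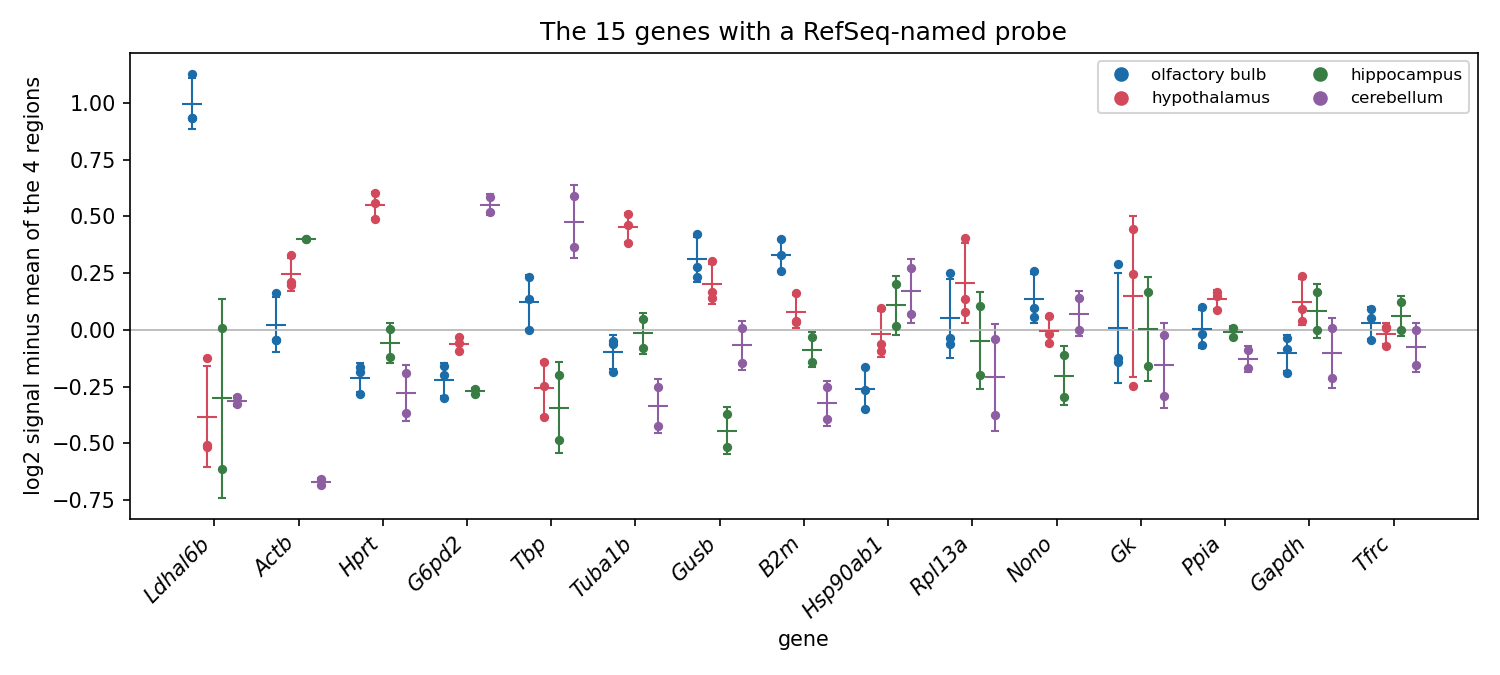
Log2 signal of the 15 named genes (x axis) relative to each gene's mean over the 4 regions (y axis), with 1 point per array, coloured by region, and bars for the mean and SD. Actb lies 1.07 lower in the cerebellum than in the hippocampus and Ldhal6b 1.38 higher in the olfactory bulb than in the hypothalamus, each in the same direction under quantile normalization and normexp.

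Probes named for lincRNAs, long intergenic noncoding RNAs, varied less between regions than probes with array-design IDs. Of 1432 lincRNA-named probes tested, 105 (7.33%) differed between the regions, against 36.8% of 54335 array-design probes (Fisher's exact test, two-sided, p 7.24e-146). Of the 1432, 851 carry human lincRNA names (6.23% differing), 504 mouse lincRNA names (8.33%) and 77 names of mm9 lincRNA exons (13%), and the files do not say how well the human-named probes match mouse transcripts. In 10000 sets of array-design probes matched on mean signal, 31.1% differed on average (permutation p 0.0002, two-sided, the smallest these sets can give). By limma, 7 lincRNA-named probes were at least 2-fold higher in the olfactory bulb than in each other region, 9 in the cerebellum, and 0 in the hypothalamus and in the hippocampus. At an unadjusted p under 0.05 these numbers were 7, 10, 1 and 0, and with slide as a block 7, 13, 0 and 1, in the order olfactory bulb, cerebellum, hypothalamus, hippocampus. At least 2-fold lower than in each other region were 5 lincRNA-named probes in the hypothalamus, 4 in the cerebellum and 3 in the hippocampus. In the cerebellum, humanlincRNA1086-_P1 lay 3.23 (SE 0.32) above the other regions (adjusted p 0.000174), and in the olfactory bulb, humanlincRNA1535-_P1 lay 2.36 (SE 0.10) above them (adjusted p 1.93e-06). Probes are not independent replicates, and this comparison was chosen after the files were seen.

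Signal at the 3′ end of a transcript against its 5′ end was measured for Pgk1 and Gapdh, and no test of it was run. The RNA was labelled by random priming, and the 2 genes differed widely on the same arrays. The size of these values therefore cannot be read as RNA quality. The 3′ probe of Pgk1 exceeded its 5′ probe by 7.56 ± 0.16 (SD, n = 2) on the log2 scale in the cerebellum, 7.38 ± 0.14 (SD, n = 3) in the olfactory bulb, 7.21 ± 0.15 (SD, n = 3) in the hypothalamus and 7.18 ± 0.17 (SD, n = 2) in the hippocampus. On slide 1 this difference was 7.45 in the cerebellum and 7.04 in the hypothalamus, and on slide 2 it was 7.67 and 7.29. For Gapdh the region means lay between 1.155 and 1.211, within the unpaired spread of the arrays (SD 0.0779 to 0.141). The slides went the other way, with 1.26 in the cerebellum on slide 1 and 1.095 on slide 2. Within slides the olfactory bulb lay above the hypothalamus, at 1.296 against 1.268 on slide 1. The values were 1.143 against 1.061 on slide 2 and 1.194 against 1.136 on slide 3. Each region occupied 1 fixed position on the slides, so slide position and region cannot be told apart.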

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

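The tests on repeated scans and the tile values by brightness were chosen only after the result was seen. Signal lay outside the main measurement in 2 places. Of 15 probes named as negative, 2 were well above background on all scans, with processed signals of 44.8 to 114 and of 92.2 to 185. Of 12 control probes with ERCC names, 10 were well above background on all scans.

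The near-identity of replicates 1 and 3 in the hippocampus and in the cerebellum was set against separate arrays, whether of 1 RNA or of 2 animals. Separate arrays were argued against by non-uniform spots, of which the pairs shared 35 and 5 and no other pair more than 1 (hypergeometric p for spots marked independently 2.99e-103 and 3.13e-16). A second scan of the same array is a candidate explanation from these same spots. The p-values test only whether spots were marked independently, and that of the cerebellum rests on 5 spots. Deviations of copies of the RefSeq-named probes from their probe mean were compared too, with the smooth trend over the array taken off. They correlated at r 0.974 in the hippocampus pair and 0.976 in the cerebellum pair, and at most 0.886 in any other pair.

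Olfactory bulb replicates differed 2-fold or more in 8021 of 51264 probes (15.6%). Position on the array may account for part: 48 tiles held up to 37.8% of the variance of a replicate difference, but 0.21% of the variance of mean level. The 12 tiles with the most of these probes, picked from the same counts, held 53.6% of them. Position was not particular to the olfactory bulb. Tiles held up to 25.2% of a replicate difference in the hypothalamus, 24.2% in the hippocampus and 11% in the cerebellum. Tile shifts on olfactory bulb replicate 1 ran from -0.756 to 0.498 among the dimmest of 4 classes of probes and from -0.0383 to 0.14 among the brightest. A difference between slides stays open, as 57.8% of the probes remained 2-fold apart after a slide shift was taken off (5040 of all compared were then apart), against 47.9% (4886) after shifts by tile and brightness, estimated from these same arrays, were taken off. Probes regional among the other 3 regions were 0.31 times as frequent among these probes as among all (0.353 outside the 12 tiles). This cannot decide on a varying share of other brain tissue. Probes that vary between replicates are less readily called regional, and tissue outside the regions profiled was not covered. Differences between animals were not tested, and the slide shift would hold them too if replicate numbers follow the animals.

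More probes were lower than higher in the cerebellum against each other region (ratio 1.19, and 1.15 to 1.59 leaving out each array). Scaling to the 75th percentile was argued against as the whole cause, since lower outnumbered higher probes under quantile normalization (1247 to 1061). This was the only other scaling run. The authors' values (1251 to 1068) looked quantile-normalized themselves and are not a separate test. Background and dim probes cannot be told apart from a regional difference, as the ratio fell to 1.05 under normexp, a background correction (849 lower, 808 higher), but was 1.17 among probes well above background on all scans, between the bounds set beforehand. The slide stays open, since with slide as a block the ratio was 1.11 (1255 lower, 1133 higher), and probes 2-fold from the mean of the other regions were 2616 higher and 3943 lower on slide 1 but 5259 and 3052 on slide 2. A biological difference of the cerebellum itself stays open and untested, as does its fixed slide position.

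Chance assignment of arrays was argued against for the test over 4 regions. There 1 of 100 splits, the real one, gave a count as large (20406, highest other 1907), the smallest share these splits can give. Against the mean of the others, the real count was also the largest for each region. These were the olfactory bulb (3139, highest other 1377), the hypothalamus (3194, 2272), the hippocampus (2948, 2762) and the cerebellum (4985, 2920). Such splits mix the regions, so they bear on whether any regions differ and not on 1 region alone. When regions were reassigned within each slide, which keeps the slides balanced as in the real split, the highest others were 7202, 2369, 2277, 3243 and 3785 in that order. The hippocampus count was then matched by 2 of 100 splits, the real one included, and the larger one had put both cerebellum arrays in the hippocampus group. For the olfactory bulb against the hypothalamus, 10 splits are too few for a share under 0.05, with 4370 probes in the real split and at most 2 in another.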

How the results depend on the processing

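The settings for normexp, for counting scans and for position were chosen after seeing the data. Of 321 total counts under alternatives, 319 stayed within 1.5 times the reported count. Normexp on the median spot signal gave 2084 probes for the olfactory bulb and 1896 for the hippocampus against the mean of the others, and the cause was not tested. Directional counts moved more, as given with each region, and hippocampus-specific probes were 72.5% higher under normexp (379 against 144), 45.2% without hippocampus replicate 1 and 61.6% as reported. With the replicate block, which is also the slide block, 30538 probes differed between the regions, and beyond the named genes given above no call of a named probe changed. Counting 12 scans separately, as the design had them, gave 26602. Of 675 values of named probes and genes under alternatives, 658 kept their direction and side of the threshold, 7 lost the call, 9 gained it and 1 reversed: Ppia, at -0.22 under quantile normalization. Hsp90ab1, cerebellum against olfactory bulb (log2 0.43, adjusted p 0.0343), lost its call without either cerebellum array, or without replicate 2 or 3 of the olfactory bulb or of the hypothalamus (adjusted p 0.0509 to 0.217). Where 1 array of a region was left, it was assumed to vary like the others. With 1 shift per tile taken off for position, 18368 probes differed between the regions, but copies of the RefSeq-named probes spread more on every scan except olfactory bulb replicate 3 (0.256 against 0.0779 on its replicate 1). With shifts by tile and brightness 20270 differed, 17490 of them among the 20406, and copies still spread more on most scans. The largest median shift of a contrast was -0.115, under normexp. The authors' table lacks the 15 named genes. Normexp on the mean spot signal, gene list tests and counts per gene were not run. Of the region-specific higher probes, 143 in the olfactory bulb, 97 in the hypothalamus, 44 in the hippocampus and 87 in the cerebellum were well above background on no scan of at least 1 other region, so signal over background limits their folds.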

Other observations

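The comparison of strand pairs was chosen after the data were seen. Some probes marked 2 regions together. The olfactory bulb and the hypothalamus both exceeded the 2 other regions in 293 probes, the hypothalamus and the hippocampus in 290, and the olfactory bulb and the hippocampus in 275. The cerebellum was higher together with another region in fewer probes: 239 with the olfactory bulb, 131 with the hypothalamus and 109 with the hippocampus. By the same rule, each count is also that of probes lower in the 2 remaining regions together. Read so, the cerebellum was lower together with the hippocampus in 293 probes, the olfactory bulb in 290 and the hypothalamus in 275. These exceed the counts of lower probes for pairs without it.

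Of 876 lincRNA loci with a probe on each strand, 521 had both strands tested. The plus strand alone differed between regions at 40 loci, the minus strand alone at 35, both at 1 and neither at 445. These counts were not set against those expected by chance. Across all 10 arrays, the strands of a locus correlated at a median r of 1.18e-05. Strands re-paired between loci gave -0.00129 (p of the re-pairing test 0.5). With region and slide means taken off, the median r was 0.0191 against 0.00698 (re-pairing p 0.4). No relation between the strands was therefore seen.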
